A study of Mus musculus with 6 samples.

How the data were processed

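Single-cell RNA sequencing was done on germ cells of mouse fetal testes at embryonic day 14.5. The labels' protocols describe cells sorted by flow cytometry for tdTomato, a red fluorescent protein, and libraries made with 10x Genomics Chromium v2 chemistry, which reads the 3' end of each transcript and marks each molecule with a unique molecular identifier (UMI). The samples were 3 controls labelled wildtype and 3 samples labelled Rb1 cKO, a conditional knockout of the retinoblastoma gene, all on a mixed background of C57/B6 and 129. The labels give neither the deleted exon nor the Cre driver.

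The deposited table holds UMI counts as whole numbers for 27998 gene symbols in 5160 cell barcodes, with no row that names no gene. The submitters' processing notes name Cell Ranger, Seurat 3.0 and the genome build mm10, without parameters. The annotation release behind the counts was not given in the sources used here. A second deposited file gives each barcode's sample and the authors' cluster number, from 5 clusters without cell type names. Barcodes held 397 to 4946 genes and at most 6.47% mitochondrial UMIs. These limits look like an earlier filter by the authors, but no label states one. Each barcode carried its sample's name, and 0 barcodes failed to match 1 sample.

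Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, which removed 6 barcodes and left 5154. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 from 2000 variable genes, 30 principal components and 15 neighbours, at resolution 1, which gave 10 clusters. A cluster was named from 9 marker lists when at least 3 markers of a type each had a UMI in 20% of its cells and its 10 leading genes did not hold more markers of another type. A cluster of low depth with none of its type's markers among those 10 stayed unnamed. Scrublet, run per sample, called 139 cells doublets, or 2.70%. They were kept and removed in an alternative, since the labels do not say how doublets had been treated.

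For cell-cycle scores, each cell was thinned to 10000 UMIs, the largest of the depths considered that kept at least 80% of cells in every sample. This left 4698 cells. The cells left out as shallower numbered 43, 13 and 218 in controls 1 to 3 and 25, 91 and 66 in cKO 1 to 3. Cells were called G1, S or G2/M by scanpy from the S phase and G2/M phase lists. Only 3 cells were called G1, so the planned comparison of G1-called cells could not be run. In its place, and after seeing this, both scores were centred on the mean of the 6 sample means, and cells below that mean in both were taken as a class of low cycle scores. The class is a range of the scores and not a cell type.

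Raw counts were summed per sample over all germ-like cells, so that the sample and not the cell was the replicate. The summed counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust dispersion, filterByExpr, TMM factors and no covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. CPM values of genes are those of the summed libraries scaled with the TMM factors, and those of marker lists are without these factors. The 17 pathway lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Values per sample were compared by exact two-sided permutation tests over 20 labelings, for which the smallest possible p is 0.1. Nothing in the labels says that the replicates came from separate animals or litters, so p-values measure the spread between these samples, which may be technical.

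Simulated libraries for the comparison of all germ-like cells held 200 changed genes in 5 draws. These 200 were taken from genes with a mean of at least 20 CPM, which 4938 of the 11540 genes tested reached. Of them, edgeR recovered 64.8% of genes changed 1.5-fold and 96.4% of those changed 2-fold, and it called 0.142% of unchanged genes. Recovery of genes below 20 CPM, such as Rb1, was not simulated. With so many changed genes in each draw, the adjusted threshold was easier to pass than in data with few changes. The draws also held no differences shared by many genes of a library. These rates therefore do not give the recovery to expect in the measured data. There 2810417H13Rik, with a log2 fold change of 0.58, had an edgeR adjusted p of 0.415. The E2F target list raised 1.2-fold was called by camera in 5 of 5 draws with the preset correlation and in 3 with an estimated one. In the same simulated draws, 0 of 60 tests of lists with no changed member were called. Genes were drawn independently in the simulation, while the estimated correlation within the measured lists reached 0.421 for ribosomal proteins. These draws therefore cannot show how often camera with the preset correlation calls correlated lists without a change. The total UMIs behind each sample ran from 7598511 to 17323152. Spread between libraries also limited the precision, with a common biological coefficient of variation of 0.15 in the fit. Pairs of samples within a group differed by a chi-square of 4.64 to 25.4 per degree of freedom, well above sampling noise, so no library was counted as a duplicate.

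Genes were named by a rule fixed before the data were examined, together with the lists and the alternative settings. Rb1 came first. Next came the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes past the adjusted threshold, with a mean of at least 20 CPM and no overlap between the groups. From each pathway list came up to 4 members past the threshold or, where none passed, the 2 with the highest mean CPM. For G1-called cells only genes already named were to be given. The rule gave 33 genes. Others named in the text were chosen after their values were seen, as stated there, and some called genes are not reported here by name. Coordinates are from the GENCODE mouse release M21 annotation of mm10. Of the 11540 genes tested, 11481 matched 1 annotated gene. The alternative settings were DESeq2 1.42.0, RLE factors, no low-count filter, a replicate block, leaving out each sample, removing doublets, a stricter cell filter of 2000 genes and 5% mitochondrial UMIs, all barcodes, equal cell numbers, clustering at resolution 2 and a fit without the robust option. S-called cells, G2/M-called cells, cells of low cycle scores, and replicates 1 and 2 alone were added after seeing the data.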

Results

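Germ cells of the fetal mouse testis were compared between 3 control and 3 Rb1 cKO samples at embryonic day 14.5, when male germ cells are leaving the mitotic cycle. Rb1 encodes the retinoblastoma protein, which binds E2F transcription factors and restrains entry into S phase. The comparison asks what loss of Rb1 does to the transcripts of these cells. The controls held 784, 430 and 1354 barcodes and the cKO samples 480, 948 and 1164. Summed UMIs were 10944893, 7598511 and 17323152 in the controls and 7807571, 12600048 and 16810763 in the cKO samples.

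Rb1 transcripts were lower in each cKO sample than in each control. Rb1, on chromosome 14 from 73183673 to 73325822, had 8.71 ± 1.60 CPM in controls and 3.57 ± 0.196 CPM in cKO samples (SD, n = 3 each). The controls stood at 10.3, 8.65 and 7.13 CPM and the cKO samples at 3.35, 3.73 and 3.64 CPM. Its log2 fold change was -1.27 ± 0.19 (SE), with an adjusted p of 0.415 by edgeR, which did not pass the threshold, and of 0.0479 by DESeq2. edgeR gave an adjusted p of 0.0422 without control 3 and of 0.0181 without a low-count filter, and the range over all 19 alternatives was 0.0181 to 0.9999. The value rests on 27 to 119 UMIs per sample, and since 3' tags can lie outside the deleted part and the labels give neither the deleted exon nor the Cre driver, the value may check nothing about the deletion.

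The 5154 cells that passed the filter all fell in clusters named germ cell-like. Germ cell markers such as Dazl, Ddx4, Dppa5a and Pou5f1 summed to 10590 ± 503 CPM in controls and 10270 ± 439 CPM in cKO samples (SD, n = 3 each). No cluster was named for another testis cell type, but cells were named by cluster, so a few other cells inside a germ cell-like cluster would not be seen. At resolution 2, 41 cells led by Pf4, Gm26870 and Tmsb4x, with a median of 2606 UMIs, stayed unnamed. Their 10 leading genes included Dlk1, of the interstitial stromal list. It stood at 189 CPM in these cells and at 6.31 CPM or less in the other clusters of resolution 2. Markers of other types stayed low in the summed libraries: the Leydig cell list reached 55.5 ± 4.89 CPM in controls and 58.1 ± 5.31 CPM in cKO samples, and the endothelial list 59.5 ± 10.9 and 53.9 ± 8.45 CPM. The interstitial stromal list stood at 7.24 and 5.49 CPM, the peritubular myoid list at 21.1 and 20.7 CPM, the macrophage list at 6.84 and 3.46 CPM and the mesonephric or surface epithelial list at 7.06 and 6.43 CPM. Control 3 had 42.0 CPM of Sertoli cell markers, against 15.2 to 23.6 CPM in the other 5 libraries. Erythroid markers stood at 6.15 CPM in cKO 1 and between 21.4 and 33.5 CPM in the others. Exact permutation p ranged from 0.2 to 1 over the 9 lists, where 0.1 is the smallest possible.

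Across all germ-like cells, no single gene changed past the threshold. edgeR tested 11540 genes and called 0 at an adjusted p under 0.05, with 205 higher and 200 lower in cKO samples at an unadjusted p under 0.05. These 405 genes are a smaller share of the genes tested than the 0.05 that arises without any change. Other groupings of the samples into equal groups gave 236 to 985 such genes. Leaving out 1 library moved the counts of higher and lower genes, to 413 and 510 without control 1, 132 and 135 without cKO 1, and 179 and 111 without cKO 2. DESeq2 called 3 genes, 1 higher and 2 lower. Groups did not overlap for 8.93% of genes, where chance gives 10%. The 5 genes that follow were chosen after their values were seen, because DESeq2, or edgeR without a low-count filter, called them beside Rb1. The smallest p belonged to 2810417H13Rik, named Pclaf in the annotation, a PCNA-associated factor of DNA replication, at 35.5 ± 1.49 CPM in controls and 53.1 ± 3.37 CPM in cKO samples. Its log2 fold change was 0.58 ± 0.09 (SE), with an edgeR adjusted p of 0.415. Fam111a had a log2 fold change of 1.29 from 2.77 to 6.88 CPM, with 15 UMIs in its lowest sample. Rab35, a small GTPase of membrane traffic, had -0.68, Nme2 had -0.81 and Rnaset2b had -1.06. Nme2 shares its locus with Gm20390 in the annotation and Rnaset2b has a close paralog, Rnaset2a, so their counts are uncertain. Their edgeR adjusted p with the filter lay between 0.415 and 0.612. Without control 3, edgeR called 4 genes, among them Rb1, the pseudogene Gm8730 and Cox18.

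**Figure D1:**
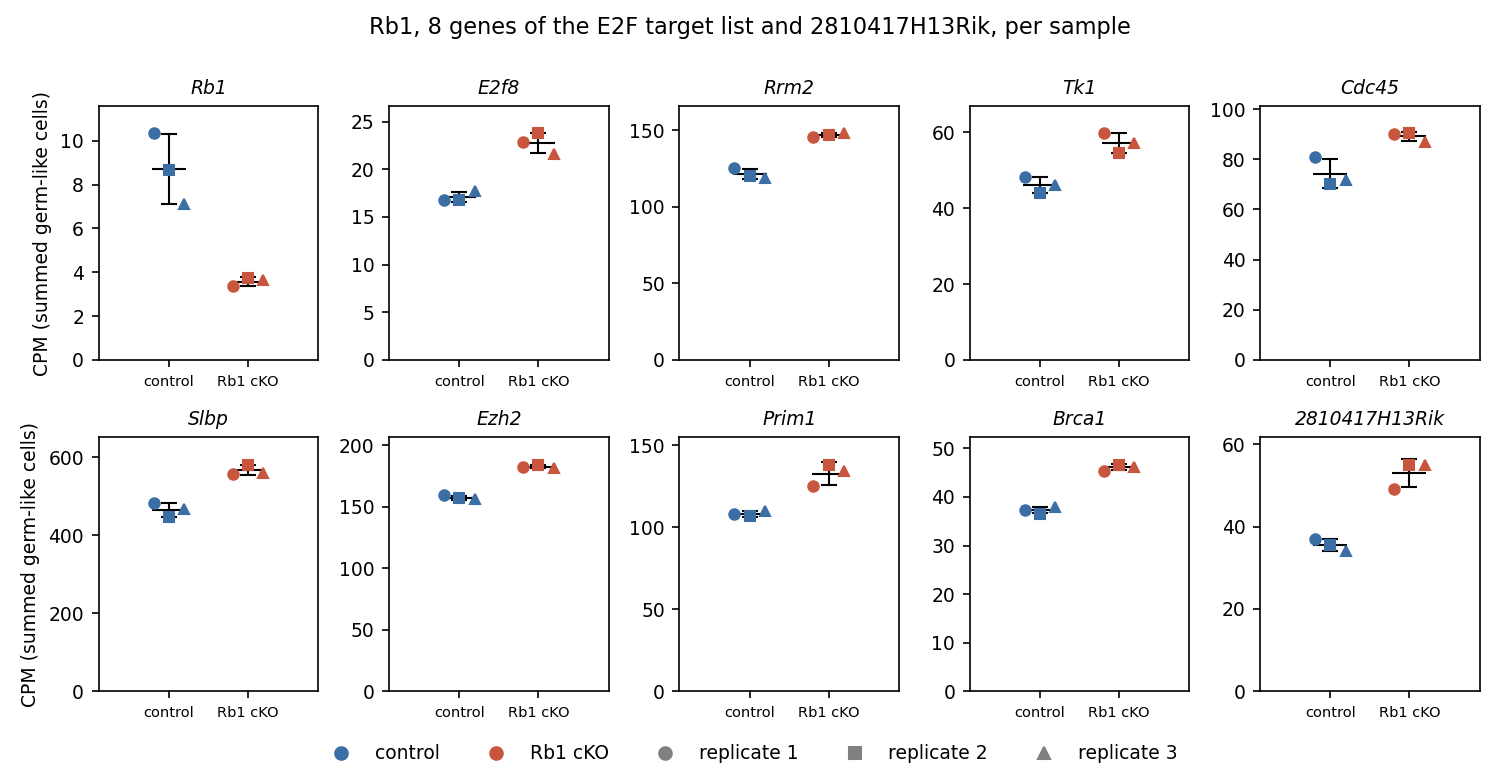
CPM of Rb1, of 8 genes of the E2F target list and of 2810417H13Rik in each summed library (y axis, from 0), with controls in blue and Rb1 cKO samples in red, and the mean and SD as black bars. Rb1 lies at 7.13 CPM or above in controls and at 3.73 CPM or below in cKO samples, and the other 9 genes are higher in each cKO sample than in each control.

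Genes of DNA replication stood higher in the cKO samples as a group. In the E2F target list, 42 of 44 measured genes had a positive log2 fold change, with a median of 0.16, and in the S phase list 43 of 43 did, with a median of 0.18. Both lists rose by camera with the preset correlation, with adjusted p of 5.71e-14 and 1.60e-20. With an estimated correlation their adjusted p were 0.0745 and 0.0547, so neither passed. Over 18 alternatives with an estimated correlation the E2F targets passed in 2, at adjusted p of 0.0457 with RLE factors and 0.0299 without cKO 1. The S phase list passed in 5, at adjusted p of 0.0257 without cKO 1 and up to 0.0457 in the others. Fry gave 0.105 and 0.0167, and for the S phase list 0.0569 to 0.107 when any library but cKO 1 was left out. Without cKO 3 the median of the E2F targets was 0.10. Of the E2F targets, 22 are also in the S phase or G2/M phase list. No member passed over all genes tested. Adjusted over the list alone, 8 E2F targets and 4 S phase genes passed, all of them higher in cKO samples, and 4 genes are shared between these sets. Without control 2, or without any 1 of the cKO samples, 0 members of either list passed in this way, against 9 and 9 without control 1 and 7 and 5 without control 3. All but Slbp were named after their values were seen. Slbp, which binds histone mRNA, had 465 ± 17.9 CPM in controls and 567 ± 13.1 CPM in cKO samples. Rrm2, a subunit of ribonucleotide reductase, had 121 ± 3.33 and 147 ± 1.35 CPM, and Prim1, a DNA primase subunit, 108 ± 1.65 and 133 ± 6.92 CPM. E2f8 had a log2 fold change of 0.41, Tk1 0.31, Brca1 0.30, Cdc45 0.26 and Ezh2 0.21. Hells, with the highest mean in both lists, had a log2 fold change of 0.16 ± 0.09 (SE). E2F targets summed to 5079 ± 54.2 CPM in controls and 5641 ± 322 CPM in cKO samples (SD, n = 3 each), without overlap, and the exact permutation p was 0.1, the smallest it can be.

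Genes of the G2 and M phases did not pass as a list over all germ-like cells. In the G2/M phase list 31 of 54 measured genes had a positive log2 fold change, with a median of 0.03 and a camera adjusted p of 0.294. Without control 1 the median was -0.01 with 25 positive, and without cKO 1 it was 0.00 with 27 positive. Hmgb2 had 0.08 and Cks2 -0.05. The G1 cyclins and CDKs had a median of 0.04 with 8 of 12 positive and an adjusted p of 0.619 by camera. Leaving out 1 library gave this list medians from 0.02 without cKO 1 to 0.09 without control 2. Within that list Cdk4 had 0.06 and Ccnd3 -0.25. The CDK inhibitors and pocket proteins rose by camera, with a median of 0.17, 7 of 10 positive and an adjusted p of 0.00242. Estimating the correlation gave an adjusted p of 0.314. Cdkn2a had a log2 fold change of 0.14 and Cdkn1a 0.20, with ranges of -0.01 to 0.26 and 0.13 to 0.27 when 1 library was left out. Without control 3 the list's median was 0.11 and its adjusted p 0.0715 by camera. Without cKO 2 they were 0.11 and 0.0281. No member of these 3 lists passed when adjusted over the list alone.

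Genes of meiosis were also higher as a list. Of 27 measured members 26 had a positive log2 fold change, with a median of 0.23 and a camera adjusted p of 1.82e-07, against an adjusted p of 0.314 with an estimated correlation. Adjusted over the list alone 1 gene passed, Smc1b, a cohesin subunit of meiotic chromosomes, which was named after its value was seen and had 181 ± 14.4 CPM in controls and 242 ± 13.4 CPM in cKO samples. Smc3 had a log2 fold change of 0.08 and Syce2 0.03. With replicates 1 and 2 alone, an alternative chosen after seeing the data, the median was 0.10 and the list's adjusted p 0.295 by camera, and without cKO 3 they were 0.11 and 0.0121. Smc1b did not pass over the list alone without control 2 or without cKO 3.

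Pluripotency and primordial germ cell genes fell as a list, with 3 of 23 positive, a median of -0.12 and a camera adjusted p of 0.00133, against an adjusted p of 0.362 with an estimated correlation. Dppa5a had 4439 ± 704 CPM in controls and 4003 ± 341 CPM in cKO samples, and Dppa3 had a log2 fold change of -0.01. The library control 3 set much of this value, since without it the median was -0.03 and the adjusted p 0.168 by camera. In the Nodal pathway Lefty1 had 0.22 and Lefty2 -0.12, with ranges of 0.06 to 0.44 and -0.19 to -0.07 when 1 library was left out. The Nodal list had a median of -0.10 with 4 of 11 positive and a camera adjusted p of 0.0772. It passed without cKO 1 at an adjusted p of 0.0448 and with equal cell numbers at 0.00348, against adjusted p of 0.418 and 0.147 with an estimated correlation, and leaving out 1 library gave medians from -0.19 without control 1 to -0.03 without control 3. The piRNA and de novo methylation genes, which silence transposons in fetal male germ cells, had a median of 0.11, 17 of 23 positive and a camera adjusted p of 0.0588. Its adjusted p by camera was 0.0187 without control 1, 0.0185 without cKO 1 and 0.0434 without cKO 2, against adjusted p of 0.693, 0.541 and 0.491 with an estimated correlation. Without a low-count filter the list also passed by camera, at an adjusted p of 0.0318, against 0.582 with an estimated correlation. Without control 3 its median was 0.04 at an adjusted p of 0.728 by camera, and without cKO 3 it was 0.04 at 0.440. Among these Dazl had 1110 ± 158 CPM in controls and 1239 ± 38.1 CPM in cKO samples and Fkbp6 a log2 fold change of -0.06. Spermatogonial stem and progenitor genes had 9 of 16 positive, a median of 0.01 and a camera adjusted p of 0.786. Camera gave that list a downward direction while its median and its mean, 0.02, were positive, and leaving out 1 library gave medians from -0.10 without control 3 to 0.05 without cKO 2. Ddit4 had 0.00 and Lhx1 0.07.

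Nuclear-encoded oxidative phosphorylation genes and ribosomal protein genes fell slightly and together as lists. Their summed CPM overlapped between the groups, with exact permutation p of 0.4 and 0.5. Of 77 oxidative phosphorylation genes 6 had a positive log2 fold change, with a median of -0.07 and a camera adjusted p of 4.05e-05, and of 79 ribosomal protein genes 12 did, with a median of -0.06 and an adjusted p of 0.000221. The adjusted p with an estimated correlation were 0.569 and 0.647. Cox7c had a log2 fold change of -0.07, Atp5b -0.02, Rps18 -0.06 and Rpl13 0.01. Without cKO 1, neither passed, with medians of -0.03 and -0.01 and adjusted p of 0.0659 and 0.572 by camera. Without control 3 the medians were -0.04 and -0.03 and the adjusted p 0.0361 and 0.0955 by camera, and the ribosomal median ranged to -0.11 without cKO 3. The p53 targets and apoptosis list had 10 of 26 positive, a median of -0.06 and a camera adjusted p of 0.152, with Rps27l at -0.06 and Bax at -0.04. Without cKO 1 or cKO 2 that adjusted p was 0.0359 or 0.0260, against adjusted p of 0.541 or 0.491 with an estimated correlation, and without cKO 3 the median was 0.01 with an upward direction. Glycolysis had 10 of 24 positive and an adjusted p of 0.324, with Pkm at -0.03 and Gapdh at -0.02. Without cKO 1 its adjusted p was 0.0185 by camera, against an adjusted p of 0.541 with an estimated correlation, and without cKO 3 its median was 0.02 with an upward direction. Cholesterol synthesis had 14 of 24 positive and 0.636, with Fdps at 0.11 and Fdft1 at 0.06, and without control 3 or cKO 1 its median was -0.06 or -0.04. Mitochondrially encoded mRNAs had 9 of 13 positive and 0.619, with mt-Co3 at 0.02 and mt-Atp6 at 0.00, and without control 1 or cKO 2 the median was -0.02 or -0.01. Immediate early and heat shock genes had 8 of 14 positive and 0.423, with Hsp90aa1 at 0.06 and Hspa8 at -0.02. No member of any of the 17 lists passed over all genes tested, and none outside the E2F target, S phase and meiosis lists passed when adjusted over the list alone.

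**Figure D2:**
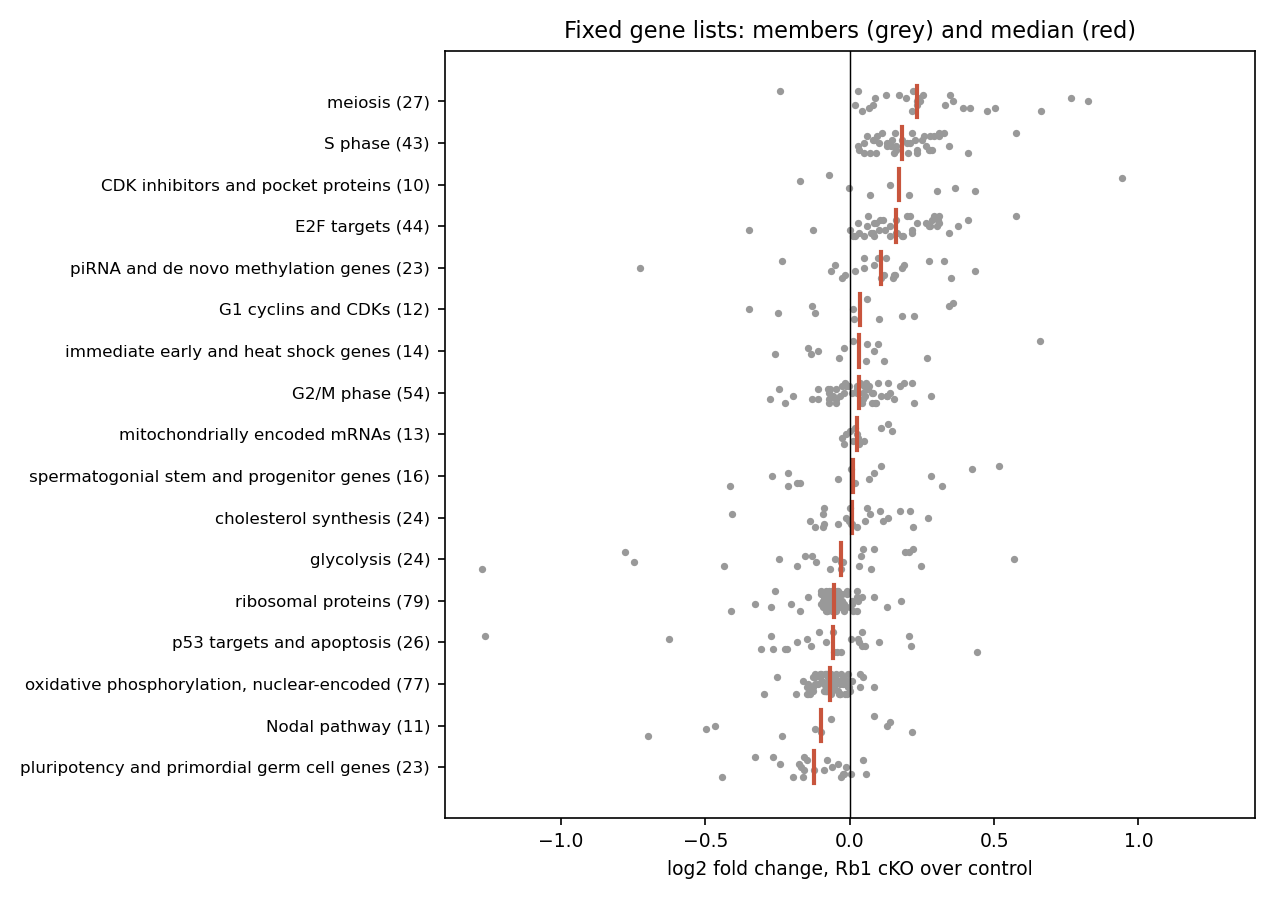
Log2 fold change of Rb1 cKO over control (x axis) for the members of the 17 fixed gene lists (grey points, number measured in brackets) and their medians (red bars). The points of the S phase list all lie above 0, those of the G2/M phase list lie on both sides of it, and medians run from -0.12 for pluripotency genes to 0.23 for meiosis.

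Of the 17 lists, camera with the preset correlation called 7, of which 4 rose and 3 fell, and without control 3 it called 4. Estimating the correlation left 0, with 2 lists at an unadjusted p under 0.05, the E2F targets and the S phase genes. Fry, which compares no list with other genes, called 1, the S phase list. Among the 7, summed CPM of the E2F target, S phase and meiosis lists did not overlap between the groups, each with an exact permutation p of 0.1. Those of the CDK inhibitor, pluripotency, oxidative phosphorylation and ribosomal lists overlapped, with exact permutation p of 0.3, 0.4, 0.4 and 0.5. This depended on the measure for the meiosis and CDK inhibitor lists. As a mean over members of log2(CPM + 1), the meiosis list overlapped, with control 1 at 4.06 and cKO 1 at 4.02. By that mean the CDK inhibitor list did not overlap, at 3.63 to 3.78 in controls and 3.81 to 3.93 in cKO samples.

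Cycle scores per cell shifted in the same direction as the S phase genes. Cells below the mean of both scores made up 23.0%, 19.4% and 21.5% of control cells and 8.35%, 11.5% and 10.6% of cKO cells, with means of 21.3% ± 1.81 and 10.1% ± 1.61 (SD, n = 3 each). The mean S score was 0.140 ± 0.00446 in controls and 0.196 ± 0.00482 in cKO samples. In both measures the groups did not overlap, and the exact permutation p was 0.1, the smallest it can be. The mean G2/M score was 0.309 ± 0.0108 and 0.321 ± 0.0126, with an exact permutation p of 0.5. Without thinning, the share of low-scoring cells was 21.1% ± 2.78 in controls and 9.14% ± 2.70 in cKO samples. The class was set after seeing the data, 1327 of 4698 cells lay within 0.05 of its limit, and the score reads the S phase list, so it is no evidence apart from that list. RNA free in the droplets also enters these scores, and its part was not measured.

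**Figure D3:**
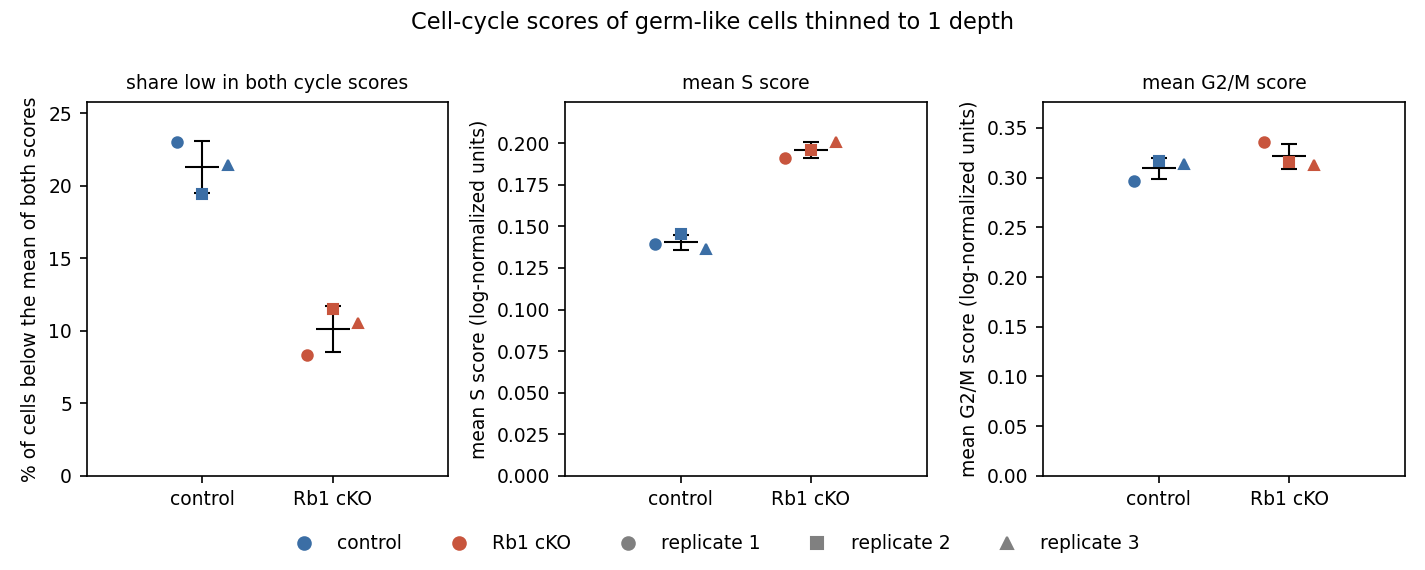
Share of cells below the mean of both cycle scores (left, %), mean S score (middle) and mean G2/M score (right) for each sample at 10000 UMIs per cell, with the mean and SD of each group as black bars. Controls lie between 19.4% and 23.0% in the left panel and cKO samples between 8.35% and 11.5%, while the G2/M scores overlap.

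The share of cells called S or G2/M was saturated. It was 99.7%, 99.8% and 100% in controls and 100% in each cKO sample, with a difference of means of 0.170 percentage points and an exact permutation p of 0.4, so it could not separate the groups. A score above 0 was enough for the call, and only 3 cells of 4698 failed it, in controls 1 and 2. S was called in 25.4% ± 4.52 of control cells and 33.1% ± 5.44 of cKO cells, with an exact permutation p of 0.2. Without thinning these shares were 15.1% ± 5.27 and 23.5% ± 3.37. Of all cells, 774 lay within 0.05 of the limit between S and G2/M.

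Depth per cell did not separate the groups. Median UMIs per germ-like cell averaged 14748 ± 2537 in controls and 14746 ± 1681 in cKO samples (SD, n = 3 each), with an exact permutation p of 1. Median genes per cell averaged 3565 ± 348 and 3588 ± 253, with an exact permutation p of 0.9, and at 10000 UMIs per cell 2896 ± 33.0 and 2914 ± 46.7, with an exact permutation p of 0.6.

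The largest spread between libraries did not follow genotype. On the first principal component, with 38.8% of the variance, control 3 stood at 37.5 and the other 5 libraries between -18.9 and 5.24. On the second, with 20%, cKO 3 stood highest at 22.2. The correlation of log2 CPM across genes, which are not independent replicates, was 0.987 between controls 1 and 2 and 0.974 between controls 1 and 3. Control 3 correlated highest with cKO 3, at 0.982. The clusters of cells also set both replicate 3 libraries apart from the other 4: the largest, of 844 cells, held 259, 152, 143 and 283 cells of controls 1 and 2 and cKO 1 and 2, but 1 of control 3 and 6 of cKO 3. Some clusters were shared by these libraries, such as 1 of 349 cells with 189 of control 3 and 138 of cKO 3, while others held mostly 1 of them, such as 1 of 705 cells with 601 of control 3 and 1 of 404 cells with 385 of cKO 3. With replicates 1 and 2 alone, an alternative chosen after seeing the data, edgeR called 2 genes and camera 6 lists, and the medians of the E2F target and S phase lists were 0.15 and 0.19. A single pair of replicate 3 libraries gives no test of its own.

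**Figure D4:**
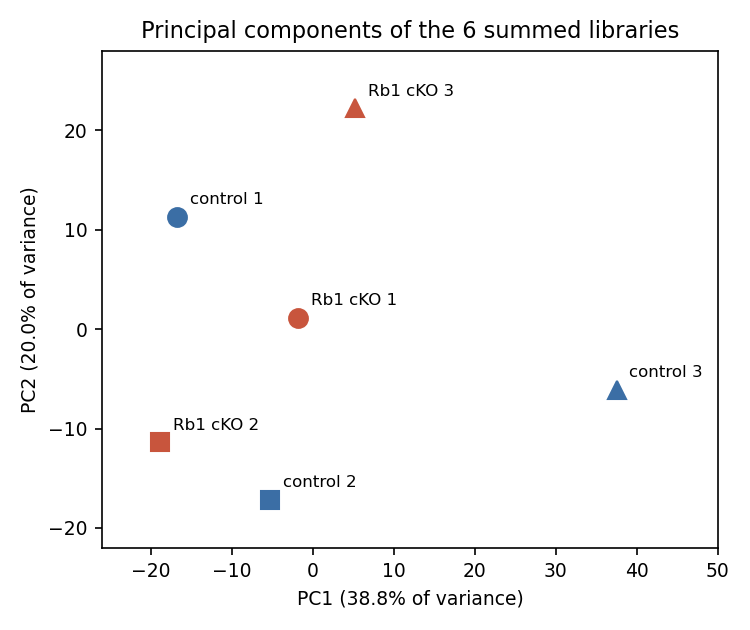
First and second principal components of log2 CPM of the 6 summed libraries (x axis 38.8% and y axis 20% of the variance), controls in blue and Rb1 cKO samples in red, with a marker shape per replicate number. Control 3 lies apart on the x axis, at 37.5, and the groups do not separate.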

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

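S-called, G2/M-called and low-scoring cells, replicates 1 and 2 alone, and centred scores were added after seeing the data. Some other fits were planned for the genes but not for the lists. These were the fits without a low-count filter or robust option, with doublets removed, a stricter cell filter, all barcodes or equal cell numbers. The count of 0 changed genes became 3 with DESeq2, 6 without a low-count filter, 2 with replicates 1 and 2 alone, and 0 to 4 with each sample left out, 4 without control 3. Without the filter edgeR called Rb1, 2810417H13Rik, Rab35, Nme2, Rnaset2b and Fam111a. The count stayed 0 in the 10 other fits that kept all 6 samples. Gm8730 was among the genes called with replicates 1 and 2. The causes were not tested. The replicate block gave 0 genes and 7 lists, and 0 E2F targets and 5 S phase genes adjusted over the list alone. With this block fry called 1 list, the CDK inhibitors and pocket proteins, at an adjusted p of 0.0377, and no longer the S phase list, at 0.0895. Same-numbered samples deviated together by correlations of -0.13, 0.23 and 0.20, and since 1 of these is under 0.1 the numbers were not taken to pair the samples, and control 1 and cKO 1 correlated best with other numbers.

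The 7 lists called became 0 with an estimated correlation and 1 with fry. Leaving out each sample gave 4 to 9 lists, 4 without control 3, and other settings 6 to 8. The E2F target and S phase lists passed camera's preset test in each of 18 other fits, with medians of 0.08 to 0.21 and 0.11 to 0.20, though 3 of these fits use cell classes set by scores from the S phase and G2/M phase lists. With an estimated correlation they passed in 2 and 5 of them. The G2/M phase list, which did not pass over all cells, passed upward in G2/M-called and low-scoring cells, at adjusted p of 0.000322 and 2.16e-05 by camera and 0.270 and 0.359 with an estimated correlation, but these cells were selected on its own score. The CDK inhibitor list, at a median of 0.0823 in low-scoring cells, was given a downward direction there, with an adjusted p of 0.829 by camera. The named genes kept their side of the threshold in 915 comparisons and passed it in 15.

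The difference in the share called S or G2/M, 0.170 percentage points, was 0 by the marker rule and 11.2 with centred scores. The marker rule asked for at least 2 UMIs of 9 cycle genes. It called 100% of cells in each sample, so it could not separate the groups. Centred scores give another share, that of cells above the mean of either score. In the other settings the difference stayed within the spread between samples. Medians of UMIs and genes per cell did so throughout. No cluster was named for a somatic type at either resolution. At resolution 2, 41 cells with a median of 2606 UMIs stayed unnamed. The planned tests of G1-called cells, and of lists in them, were not run, since 3 cells were called G1, or 1 without thinning. Depth limits Fam111a and Rb1, at 15 and 27 UMIs in their lowest samples.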

Other observations

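The cell classes by cycle score, the tests on the immediate early and pluripotency lists in control 3 and the test on the label of control 3 were chosen after the values were seen. The authors' deposited clusters give a further view of the same cells. Cluster 1, led by Cdc20 and Ccnb1, genes of mitosis, held 38.1% ± 0.339 of control barcodes and 34.5% ± 1.55 of cKO barcodes (SD, n = 3 each), without overlap, with an exact permutation p of 0.1, the smallest possible. Cluster 0, led by Stra8, Ccne1 and Gins2, held 42.7% ± 2.29 and 41.6% ± 2.54, and cluster 2, led by histone genes such as Hist1h1e, held 11.1% ± 1.86 and 13.3% ± 1.04, with exact permutation p of 0.7 and 0.2. Cluster 4, led by Phlda3, Mgarp and 1700007K13Rik, held 1.99% ± 0.334 and 1.90% ± 0.183. Cluster 3, led by Pf4 and Rpgrip1, held 1.85% of control 3 and 7.40% to 9.71% of the other 5 libraries.

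The E2F target list stood higher in cKO samples, at a median of 0.16, and the library control 3 alone does not explain it, since the median without control 3 was 0.21. Whether a larger share of cKO cells in S phase accounts for it stays open: over the 22 E2F targets outside both scoring lists, the median was 0.12 in all cells, 0.08 in S-called cells, or 64.7% of that value, 0.10 in G2/M-called cells and 0.18, over 21 genes, in low-scoring cells. The interval over genes in S-called cells, 0.01 to 0.16, leaves both a small and a large part open. Of the 10 splits of the 6 samples, 1, the real one, gave a median as far from 0, with 0.09 as the highest of the others, but 10 splits are too few for a share under 0.05. The list's unadjusted p by camera with the preset correlation was 6.72e-15 in the real split. In the others it ran from 8.88e-06 to 0.804, so small values also arose in other groupings. Each of those still sets unequal numbers of control and cKO samples against each other, and so keeps part of any genotype difference. The log2 fold change of Rb1 was 0.107 to 0.630 in size there. These values therefore do not tell whether small p-values arise without genotype.

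The count of genes was 0 in the real split, so all 10 splits gave as many, and the highest other count was 50. That split, controls 1 and 2 with cKO 2 against control 3 with cKO 1 and cKO 3, points to a structure of the samples other than genotype. For the lists, 5 of the 10 splits gave at least the 7 of the real one, and the highest other count was 7. A count of 7 lists thus also arose in other splits, but these keep part of any genotype difference. Here too 10 splits are too few for a share under 0.05.

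Control 3 stood apart from the other libraries, with 191 genes higher and 64 lower by over 1 log2 unit than the mean of the other 5. Whether reads shared with pseudogenes account for part of it stays open. Of those genes with an annotation 1.19% were pseudogenes, but only 0.479% of all genes tested were, so a high share could not arise. An immediate early and heat shock response stays open: its list lay at percentile 69.2 of 10000 random lists matched on expression, but 9 of its 14 members were higher and 5 lower, so a median near 0 does not decide. Younger embryos in control 3 may account for part of it: its pluripotency list lay at percentile 100 and its piRNA and de novo methylation list at 0.05, a hypothesis from values seen before. Extreme percentiles were not particular to these lists or to control 3. In control 3 cholesterol synthesis lay at 0 and ribosomal proteins at 99.99, while the Nodal pathway lay at 72.5. The pluripotency list lay at 0.01 in cKO 2, and the piRNA and de novo methylation list at 99.99 in control 1. Strain differences within the mixed background, and processing of both replicate 3 libraries apart from the others, stay open: 19 genes parted control 3 and cKO 3 from the other 4 libraries with a gap of over 0.5 log2 units, the second most of 15 such splits.

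Gm8730 parted controls 1 and 2 from the other 4 libraries, with 964 and 1144 CPM against 232 to 263. A mislabelled control 3 would need an Rb1 level like that of the cKO samples, and its 7.13 CPM lay above the highest of these, at 3.73, and below the other controls, at 8.65 and 10.3. This rests on the level of Rb1 tags seen in these samples, not on the deletion itself. Only 3 genes parted controls 1 and 2 with a gap of over 0.5 log2 units, where control 1 with cKO 3 gave 31. This argues against separate processing of controls 1 and 2 that moved many genes. Separate processing that moved few genes stays open, since a count of genes could not show it. Sequence variants of the mixed background at Gm8730 stay open and were not tested.

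Within 20 Mb of Rb1, 0 of 172 genes had an unadjusted p under 0.01, a ratio of 0 to the share elsewhere on the autosomes, where 53 of 10889 did (Fisher's exact p = 1). The 172 genes are too few to tell whether genes carried along with the Rb1 locus differed.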
